A study of Mus musculus with 12 samples.

How the data were processed

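The series holds stranded, poly(A)-selected RNA sequencing of 12 mouse libraries, 3 each of primary embryonic fibroblasts (PMEF), primary cortical neurons (PNeuron) and induced neuronal cells on laminin (iN_LM) and on BEM (iN_BEM). Per the submitters' processing notes, reads were mapped to mm10, and the notes name TopHat, TopHat2 2.0.13, Cufflinks and Cuffdiff 2.2.0 without saying which step each was used for. The deposited table holds log2(FPKM + 1) values for 23997 gene symbols in 12 columns, 1 per library, with the pseudocount of 1 read from the values, whose minimum is 0. The values were turned back to FPKM to apply filters and to give levels. Between 26.18% and 32.42% of genes were listed at 0 in a library, and read totals are not given in the sources used here, so the precision of a value is taken from the spread of 3 libraries. Sequencing lanes were read from the labels: all PMEF libraries, PNeuron replicate 2, iN_LM replicate 2 and iN_BEM replicate 1 ran in lane 9, the other PNeuron and iN_LM libraries in lane 1 and the other iN_BEM libraries in lane 2. Lane 2 thus held no other group, so in a fit with a lane term the iN_BEM level rests on iN_BEM replicate 1 alone.

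The design, the gene lists and the rule for named genes were written before the data were examined. Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with all 12 libraries in 1 linear model (8 residual degrees of freedom), moderated variances with an intensity trend, and Benjamini-Hochberg adjustment over the 13788 genes with an FPKM of at least 1 in at least 3 libraries, called at an adjusted p of 0.05. In all, 6 contrasts were made: PNeuron, iN_LM and iN_BEM against PMEF, iN_BEM against iN_LM, and each induced group against PNeuron. Named genes were the delivered factors, the genes with the largest increase and the largest decrease, and up to 4 members of each list. The first 10 genes in each direction were taken for iN_BEM against iN_LM, iN_LM against PMEF and PNeuron against PMEF, and the first 5 for the other contrasts. They had to pass limma, with a mean of at least 5 FPKM in the higher group, no overlap between the 3 values of each group and a symbol that is not a predicted, RIKEN, microRNA or small nucleolar RNA name. List members were those passing with the largest absolute log2 difference, then those with the highest mean FPKM. Lists comprised 25 gene lists and 8 marker lists written from general knowledge, with 408 members, all in the table, and members were also adjusted over the list alone. Lists with at least 5 tested members (30 of 33) were tested with limma's camera at its preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Reference sets were genes at least 4-fold higher or lower in PNeuron than in PMEF, followed in the iN_BEM against iN_LM contrast. Each library was also placed on the line from the PMEF mean to the PNeuron mean, and positions were compared by an exact permutation test over all splits of 3 against 3.

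Replicate numbers were checked for pairing by correlating the deviations of same-numbered libraries from their group means. All correlations were over 0.1, the limit set for pairing, for iN_BEM and iN_LM (0.46, 0.26 and 0.79 for replicates 1, 2 and 3), iN_LM and PNeuron (0.16, 0.32 and 0.65) and iN_BEM and PNeuron (0.33, 0.39 and 0.69). A shift shared by the replicate 3 libraries would also raise these correlations. In the same order 3, 4 and 4 of 6 libraries correlated best with their own number. Whether the numbers pair the libraries is therefore open, and no label states it. The contrasts with PMEF did not reach the limit, since replicate 2 had 0.03 (iN_LM), 0.02 (iN_BEM) and 0.03 (PNeuron). Alternatives were a pseudocount of 0.1, no filter and an FPKM of at least 5, quantile normalization, median-of-ratios scaling, no trend, robust moderation, a fit of the 2 groups alone, array weights, a replicate block, a lane term, each library left out in turn, a 2-fold limit for the reference sets and an axis over only the genes called between PNeuron and PMEF, and, added after the data were seen, all replicate 3 libraries left out. Gene coordinates came from GENCODE M21 (GRCm38), matched to 22652 symbols. The test was also tried on simulated data: of 100 genes shifted by 1 log2 unit it found 91%, of 100 shifted by 2 log2 units 100%, with 8 false calls (4.02% of the calls) and 0 calls in an unchanged pair. Only genes with higher mean values were shifted. The simulated noise was independent between libraries, with no lane effect and no shift shared by the replicate 3 libraries. These rates are therefore not shown to hold for genes with low values or for errors that libraries share.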

Results

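Messenger RNA was measured by stranded, poly(A)-selected RNA sequencing in 12 mouse libraries that form 4 groups of 3. The PMEF libraries came from primary embryonic fibroblasts of ICR embryos (E13.5), the starting cells of the study. The PNeuron libraries came from primary cortical neurons of ICR embryos (E14.5). The remaining groups were induced neuronal (iN) cells, which are fibroblasts turned towards a neuronal state by the transcription factors Brn2 (gene symbol Pou3f2), Ascl1 and Myt1l, cultured for 30 days. These cells grew on laminin, a standard adhesive coat for neurons (iN_LM), or on a coat that the labels abbreviate as BEM without expanding it, in a study of brain-like microenvironments (iN_BEM). The study asked how a brain-like microenvironment affects the conversion, so iN_BEM against iN_LM is the central comparison. PMEF and PNeuron give the start and the target. The deposited table listed 23997 genes as log2 FPKM. Of these, 13788 had an FPKM of at least 1 in at least 3 of the 12 libraries and were tested. Between 11629 (PMEF replicate 3) and 13245 (iN_BEM replicate 2) genes reached 1 FPKM in a library. Read totals are not given in the sources used here, so the depth behind each value is unknown. The precision rests on the spread between libraries. Levels below are mean FPKM ± SD (n = 3 libraries), and differences are on the log2(FPKM + 1) scale ± standard error from limma, which understates the change of genes with low values. No label says that the replicates were separate cultures or animals, so all p-values measure only the spread between these libraries, which may be technical. In each group replicate 3 lay farther from replicates 1 and 2 than these lay from each other, though only slightly in PNeuron. Its mean root-mean-square log2 distance to them was 1.84 (PMEF), 1.18 (PNeuron), 1.58 (iN_LM) and 1.79 (iN_BEM) times the distance between those 2.

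The delivered factors separated the fibroblasts from the other groups. Pou3f2, a POU-domain neural transcription factor, was at 0.0203 ± 0.00799 FPKM in PMEF, 17.2 ± 0.975 in iN_LM, 19.7 ± 1.13 in iN_BEM and 21.9 ± 1.43 in PNeuron. Ascl1, a proneural basic helix-loop-helix factor, was at 0.0381 ± 0.0413, 46.7 ± 5.39, 31.7 ± 5.88 and 31.9 ± 4.42 FPKM in the same order. Myt1l, a zinc-finger factor of postmitotic neurons, was at 0.0373 ± 0.00201, 12.1 ± 1.39, 30.6 ± 0.842 and 37.9 ± 2.13 FPKM. Between the substrates Myt1l was higher on BEM by 1.28 ± 0.09 (adjusted p = 4.31e-06) and Ascl1 fell by 0.55 ± 0.14 (adjusted p = 0.0109). Pou3f2 differed by 0.19 ± 0.09 (adjusted p = 0.122, and 0.0256 with the replicate number as a block). The Ascl1 call ended without iN_LM replicate 2 (adjusted p = 0.0515), with a pseudocount of 0.1 (0.0597) and with a lane term (0.164). In the GENCODE M21 annotation of GRCm38, Pou3f2 lies on chromosome 4, 22482780 to 22488366. Ascl1 lies on chromosome 10, 87490819 to 87493660 and Myt1l on chromosome 12, 29528384 to 29923213. The table holds 1 value per gene symbol, so transcripts from a delivered copy and from the gene's own locus were not separated.

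**Figure D1:**
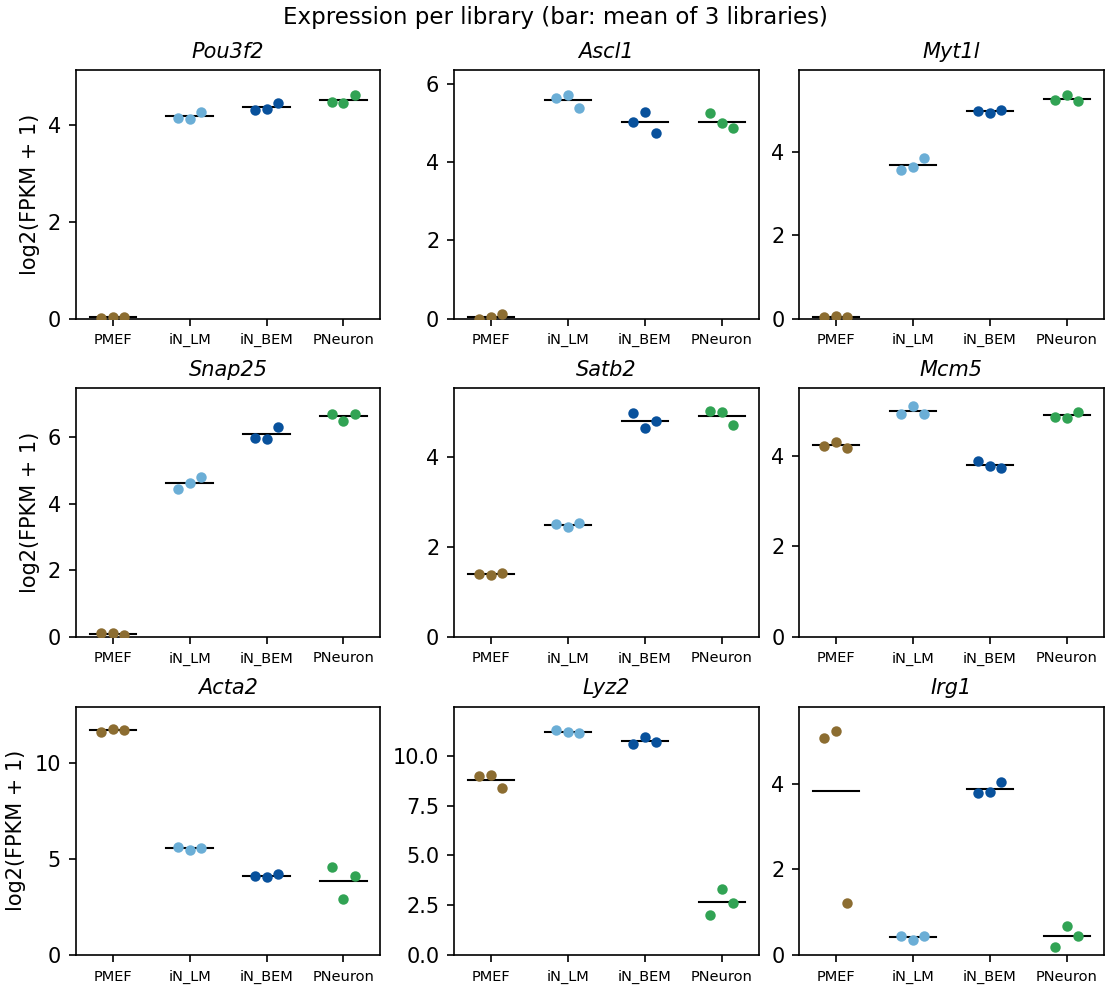
Expression of 9 genes in each of the 12 libraries, as log2(FPKM + 1) on the vertical axes, by group (points are libraries, bars are means of 3 libraries). Pou3f2, Ascl1 and Myt1l were near 0 in all PMEF libraries, Satb2 was higher in all 3 iN_BEM than in all 3 iN_LM libraries, and Irg1 was at 12.7 to 15.5 FPKM in iN_BEM and at most 0.37 in iN_LM.

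Primary cortical neurons against fibroblasts gave the reference difference between the target and the starting cells. Nsg2, which encodes a neuronal endosomal protein, was at 0.803 ± 0.0994 FPKM in PMEF and 966 ± 94.8 in PNeuron, a log2 difference of 9.06 ± 0.09. Stmn3 rose by 8.28 ± 0.14, Gpm6a by 8.04 ± 0.14, Dcx (doublecortin, a microtubule protein of migrating neurons) by 7.78 ± 0.16 and Mapt (tau) by 7.65 ± 0.13. Neurod6, a transcription factor of cortical excitatory neurons, rose by 7.76 ± 0.12, and Ttr (transthyretin, abundant in choroid plexus) by 7.28 ± 0.16. The genes that fell furthest under the naming rule included S100a4 (-10.53 ± 0.14), a calcium-binding protein common in fibroblasts, and Serpine1 (-10.28 ± 0.17), which encodes plasminogen activator inhibitor 1. So did the protease inhibitor gene Timp1 (-9.92 ± 0.21) and the chemokine gene Ccl2 (-9.63 ± 0.49). All 18 pan-neuronal, all 16 presynaptic and all 15 postsynaptic members rose, with the same counts adjusted over the list alone. Medians were 4.37, 4.05 and 2.84. Their camera adjusted p-values were 7.09e-09, 7.68e-08 and 2.13e-06, and each list had an adjusted p = 0.169 with an estimated correlation. Snap25, a component of the synaptic vesicle fusion machinery, rose by 6.54 ± 0.12 and the AMPA receptor subunit gene Gria2 by 5.27 ± 0.18. Glutamatergic and cortical identity genes rose in 14 of 14 cases, Tbr1 by 5.78 ± 0.12 among them. GABAergic genes rose in 12 of 12, Gad1 by 4.54 ± 0.18 (14 and 12 for these lists adjusted over the list alone). Their camera adjusted p was 2.95e-07 and 4.84e-06, and adjusted p = 0.169 with an estimated correlation for each. On the fibroblast side 16 of 18 identity genes fell and 1 rose (16 and 1 adjusted over the list alone), with Fn1, the fibronectin gene, at -7.57 ± 0.22 (camera adjusted p = 4.73e-06, and adjusted p = 0.169 with an estimated correlation). All 19 matrix genes fell, Lox (lysyl oxidase, a collagen crosslinker) at -8.02 ± 0.10. So did all 10 contractile smooth muscle genes, Tagln at -8.57 ± 0.31, and all 9 YAP/TAZ targets, Ctgf at -8.58 ± 0.20, with the same counts adjusted over the list alone. The camera adjusted p of these lists was 7.68e-08, 1.22e-05 and 6.7e-05, against adjusted p = 0.197, 0.169 and 0.169 with an estimated correlation. All 16 Hox genes tested fell (16 adjusted over the list alone), Hoxc6 at -4.35 ± 0.15. So did 13 of 14 macrophage and microglia markers (13 adjusted over the list alone), Lyz2 (lysozyme) at -6.15 ± 0.26. These lists had camera adjusted p = 4.73e-06 and 6.73e-04, and adjusted p = 0.197 and 0.295 with an estimated correlation. The cell cycle list moved both ways, with 7 members higher and 5 lower of 15 (8 and 6 adjusted over the list alone, camera adjusted p = 0.559). In all, 11430 of 13788 genes changed, 5342 higher and 6088 lower in neurons, and 3034 and 3531 of them by at least 2-fold, with the median gene at -0.102. Among genes named for this comparison the highest adjusted p was 6.55e-10 (Ccl2). Of 30 lists tested, 8 were higher and 13 lower by camera with its preset correlation. With an estimated correlation 0 passed (6 at an unadjusted p under 0.05), and 28 passed fry at an adjusted p under 0.05. All PMEF libraries ran in sequencing lane 9, where the PNeuron group has only replicate 2. Against that library alone the medians were 4.36 for pan-neuronal and -4.58 for matrix genes.

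The iN_LM libraries, taken after 30 days, held transcripts, many but not all of them neuronal, that the starting fibroblasts lacked or had at low levels. Agtr2, the angiotensin II type 2 receptor gene, was at 0.581 ± 0.386 FPKM in PMEF and 290.3 ± 36.1 in iN_LM (7.54 ± 0.19). Sst, the somatostatin gene of inhibitory interneurons, was at 0.249 ± 0.0254 and 208 ± 21.6 (7.38 ± 0.21). Nsg2 rose by 7.31 ± 0.09, Stmn3 by 6.88 ± 0.14, Dcx by 6.24 ± 0.16, the imprinted hydrolase gene Mest by 7.11 ± 0.16 and Ttr by 6.23 ± 0.16. Of single genes Serpine1 fell to a difference of -7.52 ± 0.17, the prostaglandin synthase gene Ptgs2 at -7.13 ± 0.16, the smooth muscle actin gene Actg2 at -6.87 ± 0.14 and Tagln at -6.25 ± 0.31. Among the pan-neuronal genes 17 of 18 rose and 1 fell (17 and 1 adjusted over the list alone), with a median of 3.30 (camera adjusted p = 4.55e-08, and adjusted p = 0.129 with an estimated correlation). Presynaptic genes rose in 16 of 16 cases, Snap25 by 4.53 ± 0.12, and postsynaptic genes in 15 of 15, Gria2 by 3.50 ± 0.18 (the same counts adjusted over the list alone). For these synaptic lists camera gave adjusted p = 4.53e-07 and 3.51e-05, and adjusted p = 0.181 with an estimated correlation for each. The 14 glutamatergic and cortical identity genes all rose (14 adjusted over the list alone), including Neurod6 (5.89 ± 0.12), Lhx2 (5.49 ± 0.13) and Tbr1 (4.69 ± 0.12), transcription factors of the embryonic cortex (camera adjusted p = 5.64e-07, and adjusted p = 0.11 with an estimated correlation). So did the 12 GABAergic genes (12 adjusted over the list alone), Gad1 by 4.17 ± 0.18 (camera adjusted p = 5.4e-06, and adjusted p = 0.162 with an estimated correlation). RNA or cells of a cortical preparation would bring the same genes, Ttr and Sst among them, and these libraries do not exclude that source. Of the neural progenitor genes 8 rose and 2 fell of 10 (8 and 2 adjusted over the list alone), Fabp7, a fatty acid binding protein of radial glia, by 5.35 ± 0.20 (camera adjusted p = 0.00315, and adjusted p = 0.129 with an estimated correlation). Of the Ascl1 and Notch pathway targets 10 of 12 rose with 2 lower (10 and 2 adjusted over the list alone), Insm1 by 4.54 ± 0.19 (camera adjusted p = 0.00123, and adjusted p = 0.183 with an estimated correlation). Of the lists of fibroblast genes some fell and the identity list did not pass. All 10 contractile genes fell (10 adjusted over the list alone), with Cnn1 at -6.53 ± 0.13 and Acta2, smooth muscle actin, at -6.15 ± 0.30 (camera adjusted p = 1.13e-06, and adjusted p = 0.129 with an estimated correlation). All 9 YAP/TAZ targets fell (9 adjusted over the list alone), Ankrd1 at -6.28 ± 0.09 (camera adjusted p = 1.4e-05, and adjusted p = 0.162 with an estimated correlation). In the fibroblast identity list 10 of 18 members fell and 4 rose (10 and 4 adjusted over the list alone). S100a4 fell by 4.59 ± 0.14, while Lum, encoding the collagen-binding proteoglycan lumican, rose by 5.57 ± 0.11 and Col3a1 (type III collagen) by 3.62 ± 0.17. The list did not pass (camera adjusted p = 0.164). The marker lists of other lineages gave mixed results in the same libraries. Of 12 skeletal muscle genes 10 rose and 2 fell, and 9 of 11 astrocyte, 13 of 14 macrophage and microglia and 6 of 7 adipocyte markers rose and 0 fell. Adjusted over the list alone, 10, 9, 13 and 6 members rose and 2, 1, 0 and 0 fell. Actc1 (cardiac actin) rose by 4.12 ± 0.14, Gfap, the astrocyte filament gene, by 4.26 ± 0.19, the complement gene C1qb by 2.84 ± 0.33 and Adipoq (adiponectin) by 2.72 ± 0.13. The camera adjusted p was 0.00277, 7.61e-04, 5.83e-04 and 0.00401 in that order. These lists had adjusted p = 0.11, 0.11, 0.287 and 0.287 with an estimated correlation. The skeletal muscle call also ended with an FPKM of at least 5 (0.2). Oligodendrocyte lineage markers rose in 6 of 8 cases (6 adjusted over the list alone, camera adjusted p = 0.0166, and adjusted p = 0.287 with an estimated correlation). The endothelial (3 higher and 1 lower of 5, camera adjusted p = 0.685), Schwann cell and neural crest (4 higher of 8, 0.333) and cartilage and bone lists (4 higher and 1 lower of 5, 0.083) did not pass, and of 4 epithelial markers, too few to test, 2 were higher and 2 lower (all counts the same adjusted over the list alone). Interferon response genes rose in 12 of 13 cases (12 adjusted over the list alone), Irf7 by 2.73 ± 0.18 (camera adjusted p = 1.6e-04, and adjusted p = 0.287 with an estimated correlation). In contrast, 10 of 13 inflammatory cytokine genes fell and 2 rose (10 and 2 adjusted over the list alone), Cxcl1 at -6.33 ± 0.85 (camera adjusted p = 0.0038, and adjusted p = 0.467 with an estimated correlation). In total 10572 genes changed, 5318 higher and 5254 lower on laminin than in PMEF, and 2629 and 2012 by at least 2-fold. For genes named on laminin the highest adjusted p was 1.72e-05 (Cxcl1). By camera 14 lists were higher and 10 lower of 30, with 0 passing under an estimated correlation (8 at an unadjusted p under 0.05) and 28 by fry. The oxidative phosphorylation list was lower, with 12 of 14 members fallen (12 adjusted over the list alone, camera adjusted p = 0.00307, and adjusted p = 0.183 with an estimated correlation). It took the opposite sign after quantile normalization, and median-of-ratios scaling moved the median gene to 0.13. Within lane 9, which holds all PMEF libraries and iN_LM replicate 2, the medians were 3.46 for pan-neuronal and -4.60 for contractile genes.

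The iN_BEM libraries were also compared with the starting fibroblasts. Nsg2 reached 613 ± 29.8 FPKM (8.41 ± 0.09 against PMEF), Sst 311 ± 18.4 (7.96 ± 0.21) and Stmn3 317 ± 35.4 (7.86 ± 0.14). Serpine1 fell by 8.99 ± 0.17, from 1864 ± 366 to 2.64 ± 0.591 FPKM, with Actg2 at -7.96 ± 0.14, Tagln at -7.77 ± 0.31 and Acta2 at -7.58 ± 0.30. All 18 pan-neuronal, 16 presynaptic and 15 postsynaptic genes rose, with the same counts adjusted over the list alone and medians of 4.26, 3.64 and 2.79. Mapt rose by 7.10 ± 0.13, Snap25 by 5.99 ± 0.12 and Gria2 by 5.21 ± 0.18. Camera gave these lists adjusted p-values of 4.02e-09, 5.93e-08 and 3.3e-06, and each an adjusted p = 0.148 with an estimated correlation. In the glutamatergic and cortical identity list 13 of 14 members rose and 1 fell (13 and 1 adjusted over the list alone), Neurod6 by 7.23 ± 0.12 and Neurod2 by 5.61 ± 0.18 (camera adjusted p = 2.42e-06, and adjusted p = 0.148 with an estimated correlation). Voltage-gated channel genes rose in 14 of 15 cases and fell in 1 (14 and 1 adjusted over the list alone), Kcnq2, a potassium channel subunit, by 4.04 ± 0.15 (camera adjusted p = 6.55e-06, and adjusted p = 0.186 with an estimated correlation). The 10 contractile genes all fell (10 adjusted over the list alone, camera adjusted p = 3.3e-06, and adjusted p = 0.148 with an estimated correlation). So did 15 of 19 matrix genes with 2 higher (15 and 2 adjusted over the list alone), Timp1 at -5.27 ± 0.21 (camera adjusted p = 0.00108, and adjusted p = 0.406 with an estimated correlation). Integrin and focal adhesion genes fell in 14 of 16 cases with 1 higher (14 and 1 adjusted over the list alone), Itga5 at -4.43 ± 0.18 (camera adjusted p = 1.43e-04, and adjusted p = 0.148 with an estimated correlation). Cell cycle genes fell in 10 of 15 cases and rose in 1 (10 and 1 adjusted over the list alone), Rrm2 at -2.07 ± 0.13 and Cdk1 at -1.30 ± 0.12 (camera adjusted p = 0.0123, and adjusted p = 0.384 with an estimated correlation). This list lost its call with quantile normalization (0.144), which gave it a call in iN_LM against PMEF instead (0.0136). Lum, at 5.11 ± 0.11, was again among 4 identity genes that rose while 13 of 18 fell (4 and 13 adjusted over the list alone, camera adjusted p = 0.0494, and adjusted p = 0.469 with an estimated correlation). That call ended without iN_BEM replicate 1 (0.0553) or 3 (0.0503) or PNeuron replicate 1 (0.0526) or 2 (0.0568). It also ended with quantile normalization (0.426), an FPKM of at least 5 (0.118), a pseudocount of 0.1 (0.0529), the 2 groups alone (0.0507) and array weights (0.0558). Macrophage and microglia markers rose in 13 of 14 cases and fell in 1 (13 and 1 adjusted over the list alone), Cd68 by 2.15 ± 0.25 (camera adjusted p = 0.00813, and adjusted p = 0.406 with an estimated correlation). Astrocyte markers rose in 8 of 11 with 1 lower (8 and 1 adjusted over the list alone), Aqp4, the astrocyte water channel, by 4.18 ± 0.12 (camera adjusted p = 0.00218, and adjusted p = 0.148 with an estimated correlation). Altogether 11147 genes changed, 5378 higher and 5769 lower than in PMEF, and 2968 and 2498 by at least 2-fold. For genes named on BEM the highest adjusted p was 3.84e-06 (Cd68). Camera called 13 lists higher and 11 lower, 0 with an estimated correlation (9 at an unadjusted p under 0.05), and 29 of 30 passed fry. The inflammatory cytokine list (9 lower and 3 higher of 13, the same adjusted over the list alone, camera adjusted p = 0.0271, and adjusted p = 0.549 with an estimated correlation) lost its call without PMEF replicate 1 (0.0951) or 2 (0.0629), with an FPKM of at least 5 (0.0764) and with the replicate block (0.0603). For the whole table, median-of-ratios scaling moved the median gene to 0.102 and quantile normalization to -0.103. In lane 9, iN_BEM replicate 1 against the PMEF libraries gave medians of 4.22 for pan-neuronal and -5.50 for contractile genes.

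The direct comparison of the substrates asked what BEM changed relative to laminin. Satb2, a chromatin factor of upper-layer cortical projection neurons (chromosome 1, 56793981 to 56978650), was at 4.64 ± 0.178 FPKM on laminin and 27.0 ± 3.33 on BEM, a log2 difference of 2.31 ± 0.11. Dync1i1, a neuronal dynein subunit, rose by 2.11 ± 0.14, the long noncoding RNA Snhg11 by 2.08 ± 0.13, Sertm1 by 2.07 ± 0.11 and the calmodulin kinase-like vesicle gene Camkv by 2.02 ± 0.17. Irg1, the itaconate-producing enzyme of activated macrophages, was at 0.336 ± 0.0459 FPKM on laminin and 13.8 ± 1.55 on BEM (3.46 ± 0.75). The cytokine gene Il1a (2.27 ± 0.76) rose with it, as did the scavenger receptor gene Marco (2.24 ± 0.69) and the chemokine genes Ccl5 (2.06 ± 0.54) and Cxcl10 (1.98 ± 0.67). Among the genes that fell furthest was Hbb-y, an embryonic globin (-3.17 ± 0.34, from 15.7 ± 8.12 to 0.754 ± 0.365 FPKM). Others were the growth factor gene Fgf15 (-1.88 ± 0.12), Tagln (-1.52 ± 0.31), Serpine1 (-1.47 ± 0.17), the chromatin protein gene Hmga2 (-1.43 ± 0.13) and Acta2 (-1.43 ± 0.30). The replication genes Mcm3 (-1.22 ± 0.10), Mcm5 (-1.19 ± 0.09) and Uhrf1 (-1.18 ± 0.10) fell as well. Hmga1-rs1 (-1.89 ± 0.58) is uncertain, since it is a near copy of Hmga1 and reads may be split between them. Its call ended without iN_LM replicate 1 or 2 or iN_BEM replicate 3, with no filter (adjusted p = 0.0529), with robust moderation (0.0522) and with the lane term (0.753, where the log2 difference of Hmga1-rs1 was -0.51). With single libraries left out that difference was -2.41 to -1.12.

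Lists of neuronal genes stood higher on BEM. All 16 presynaptic genes rose (16 adjusted over the list alone), with a median of 1.08. Syt4, a synaptotagmin, stood at 1.48 ± 0.13, Snap25 at 1.46 ± 0.12 and Cplx1, a complexin, at 1.41 ± 0.17 (camera adjusted p = 1.5e-13, and adjusted p = 0.0983 with an estimated correlation). Pan-neuronal genes rose in 17 of 18 cases (17 adjusted over the list alone), Mapt by 1.33 ± 0.13 and Stmn2 by 1.09 ± 0.10 (camera adjusted p = 7.64e-13, and adjusted p = 0.0983 with an estimated correlation). Of the postsynaptic genes 13 of 15 rose (14 adjusted over the list alone), Gria2 by 1.71 ± 0.18 and Camk2b by 1.55 ± 0.14 (camera adjusted p = 1.18e-09, and adjusted p = 0.0983 with an estimated correlation). Of the voltage-gated channel genes 14 of 15 rose (14 adjusted over the list alone), Scn2a1, a neuronal sodium channel, by 1.41 ± 0.14 and Scn3b by 1.24 ± 0.10 (camera adjusted p = 6.61e-11, and adjusted p = 0.109 with an estimated correlation). The glutamatergic and cortical identity list was mixed, with 6 members higher and 1 lower of 14 (7 and 2 adjusted over the list alone), Neurod6 at 1.35 ± 0.12 and Neurod2 at 1.19 ± 0.18 (camera adjusted p = 0.00713, and adjusted p = 0.309 with an estimated correlation). GABAergic genes rose in 7 of 12 cases (7 higher and 1 lower adjusted over the list alone), the neuropeptide gene Npy by 1.07 ± 0.12 and Gad1 by 1.05 ± 0.18 (camera adjusted p = 0.011, and adjusted p = 0.368 with an estimated correlation). Brain-type matrix genes rose in 4 of 10 cases and fell in 1 (4 and 1 adjusted over the list alone), with the proteoglycan genes Bcan and Ncan at 1.05 ± 0.17 and 0.95 ± 0.14 (camera adjusted p = 0.0185, and adjusted p = 0.358 with an estimated correlation). This call ended when no expression filter was applied (camera adjusted p = 0.08). In lane 9, where iN_BEM replicate 1 and iN_LM replicate 2 ran together, the medians were 1.24 for presynaptic, 0.91 for pan-neuronal and 0.89 for postsynaptic genes.

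The cell cycle and neural progenitor lists stood lower on BEM. All 15 cell cycle genes fell (15 adjusted over the list alone), with a median of -0.86. Among them were Ccnb1, the mitotic cyclin B1, at -1.03 ± 0.15, Rrm2, a ribonucleotide reductase subunit, at -1.0 ± 0.13 and Mcm2 at -1.0 ± 0.12 (camera adjusted p = 6.61e-11, and adjusted p = 0.0983 with an estimated correlation). Neural progenitor genes fell in 7 of 10 cases (7 adjusted over the list alone), the SOX factor genes Sox3 and Sox1 at -1.01 ± 0.19 and -0.68 ± 0.12 and Pax6 at -0.67 ± 0.11 (camera adjusted p = 9.68e-04, and adjusted p = 0.0983 with an estimated correlation). Ascl1 and Notch pathway targets moved both ways, with 5 lower, Hes5 at -0.80 ± 0.16 among them, and 1 higher, Zbtb18 by 1.30 ± 0.10 (5 and 2 adjusted over the list alone). That list did not pass (camera adjusted p = 0.437). With the lane term the calls of Sox3, Sox1 and Pax6 ended, and those of Ccnb1, Rrm2 and Mcm2 stayed. The lane 9 pair gave a median of -0.98 for the cell cycle and -0.69 for the progenitor list.

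Lists of contractile, matrix and fibroblast genes were lower on BEM as well. Contractile smooth muscle genes fell in 7 of 10 cases (7 adjusted over the list alone), Myl9, a myosin light chain, at -1.02 ± 0.20 next to Tagln and Acta2 (camera adjusted p = 1.91e-04, and adjusted p = 0.229 with an estimated correlation). The YAP/TAZ targets fell in 7 of 9 (7 lower and 1 higher adjusted over the list alone), the matricellular genes Cyr61 and Ctgf at -1.0 ± 0.17 and -0.92 ± 0.20 (camera adjusted p = 0.00269, and adjusted p = 0.333 with an estimated correlation). Of the matrix genes 8 of 19 fell (11 adjusted over the list alone), Timp3 at -0.69 ± 0.16 and Lox at -0.68 ± 0.10 (camera adjusted p = 1.91e-04, and adjusted p = 0.368 with an estimated correlation). Of the fibroblast identity genes 7 of 18 fell (13 adjusted over the list alone), S100a4 at -0.86 ± 0.14, Fbn1 (fibrillin 1) at -0.62 ± 0.12 and Thbs2 at -0.59 ± 0.12 (camera adjusted p = 1.23e-04, and adjusted p = 0.3 with an estimated correlation). Integrin and focal adhesion genes fell in 8 of 16 cases (9 adjusted over the list alone), Vcl (vinculin) at -0.65 ± 0.13 (camera adjusted p = 0.0117, and adjusted p = 0.333 with an estimated correlation). The Hox genes fell in 6 of 16 cases (9 adjusted over the list alone), Hoxa5 at -0.84 ± 0.14 (camera adjusted p = 8.47e-04, and adjusted p = 0.358 with an estimated correlation). Skeletal muscle genes fell in 4 of 12 cases (5 adjusted over the list alone), Acta1 at -0.74 ± 0.17 (camera adjusted p = 0.0108, and adjusted p = 0.0983 with an estimated correlation). Its call ended with a pseudocount of 0.1 (0.0667) and with the lane term (0.0822). Schwann cell and neural crest markers fell in 4 of 8 cases (6 adjusted over the list alone), with a median of -0.51 (camera adjusted p = 0.00996, and adjusted p = 0.333 with an estimated correlation). With the lane term the calls of Tagln, Acta2, Myl9, Cyr61, Ctgf, Timp3, Fbn1, Thbs2, Vcl and Acta1 ended. Those of Lox, S100a4 and Hoxa5 stayed. The lane 9 pair gave medians of -0.81 for contractile, -0.50 for matrix and -0.51 for fibroblast identity genes.

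Of the immune lists 2 were lower on BEM and 1 did not pass. Macrophage and microglia markers fell in 7 of 14 cases (11 adjusted over the list alone), Itgam, the CD11b integrin gene, at -0.82 ± 0.19, with a list median of -0.64 (camera adjusted p = 9.68e-04, and adjusted p = 0.358 with an estimated correlation). These were the same libraries in which Irg1 and Marco rose. Interferon response genes fell in 9 of 13 cases with 1 higher (9 and 1 adjusted over the list alone), Irf7 at -0.80 ± 0.18, Bst2 at -0.76 ± 0.19 and Isg15 at -0.76 ± 0.16, against Cxcl10 at 1.98 ± 0.67 (camera adjusted p = 4.94e-04, and adjusted p = 0.355 with an estimated correlation). The inflammatory cytokine list did not pass (1 higher of 13, and 1 adjusted over the list alone, camera adjusted p = 0.364), but passed without PMEF replicate 3 (0.00252), without all replicate 3 libraries (0.00267) and with the 2 groups alone (0.003). The Il1a, Marco and Cxcl10 calls each ended when any single iN library was left out, with adjusted p up to 0.0998, 0.07 and 0.117, while the log2 differences stayed at 2.17 to 2.34, 2.12 to 2.34 and 1.84 to 2.06. In a fit of the 2 groups alone, where the spread of PMEF does not enter, their adjusted p was 4.3e-05, 8.16e-05 and 8.13e-05, and without all replicate 3 libraries 2.97e-07, 1.02e-06 and 1.63e-06. With no filter the adjusted p was 0.0706 for Il1a, 0.0525 for Marco and 0.0743 for Cxcl10, and with robust moderation 0.0784 for Il1a, 0.0562 for Marco and 0.0757 for Cxcl10. The calls of Marco (0.0858), Cxcl10 (0.0588) and Irf7 (0.0593) also ended with a pseudocount of 0.1. With the lane term the calls of the lower genes Itgam, Irf7, Bst2 and Isg15 ended. The Il1a call also ended without PNeuron replicate 1, that of Cxcl10 without PNeuron replicate 1 or 2, and the Ccl5 call ended without iN_LM replicate 2 (0.0537). These genes varied between the PMEF libraries, Irg1 being at 32.3, 36.2 and 1.34 FPKM in PMEF replicates 1, 2 and 3. Irg1 kept its call in every fit with a library left out and lost it only with the lane term (adjusted p = 0.148), where the log2 difference was 3.27, while within lane 9 it was 3.41.

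Other lists moved little or in both directions. Hypoxia and glycolysis genes had 3 higher and 1 lower of 13 (3 and 1 adjusted over the list alone), the kinase gene Pdk1 at 0.84 ± 0.11. The p53 and senescence genes had 3 lower of 11 (4 lower and 1 higher adjusted over the list alone). ER and integrated stress genes had 2 lower of 12 (2 adjusted over the list alone), Atf3 at -0.60 ± 0.14. No oxidative phosphorylation gene and no adipocyte marker changed by limma, of 14 and 7 tested, nor when adjusted over the list alone. Astrocyte markers had 2 higher and 2 lower of 11 (2 and 3 adjusted over the list alone), the glutamate transporter gene Slc1a3 at 0.54 ± 0.09. Oligodendrocyte lineage markers had 1 higher, Olig2 at 0.87 ± 0.15, and 3 lower of 8 (2 and 3 adjusted over the list alone). Endothelial markers fell in 3 of 5 cases (4 adjusted over the list alone) and cartilage and bone markers in 2 of 5 (2 adjusted over the list alone). Camera adjusted p for these lists was 0.109, 0.263, 0.263, 0.303, 0.201, 0.981, 0.364, 0.079 and 0.263, in the order given. The hypoxia list passed without iN_BEM replicate 3 (0.0332), without all replicate 3 libraries (0.038) and with array weights (0.0381), and the adipocyte list without iN_BEM replicate 2 (0.0345). Lists with fewer than 5 measured members were only counted: 3 of 4 epithelial markers fell (3 adjusted over the list alone), Krt8 at -0.97 ± 0.19. Neither of the 2 measured genes of other transmitter systems passed, with Ddc (DOPA decarboxylase) at 0.09 ± 0.18 and Slc18a2 at 0.08. Across all genes 4181 changed between the substrates, 2037 higher and 2144 lower on BEM, with 260 and 34 by at least 2-fold. The highest adjusted p of a gene named here as changed was 0.0411 (Cxcl10). Camera called 7 lists higher and 12 lower, 0 with an estimated correlation (7 at an unadjusted p under 0.05), and 21 of 30 passed fry. Lane 2 held only iN_BEM replicates 2 and 3, so with a lane term the iN_BEM level rests on iN_BEM replicate 1 alone. Calls lost with that term may reflect lost information or a lane effect, and the fit cannot tell these apart. Atf3, Olig2 and Slc1a3 lost theirs, and no named gene of the neuronal lists did. With the replicate number as a block 6977 genes were called, 3942 of them lower. With sequencing lane as a term there were 1224, in which 28 of the 67 called genes named here lost their call (4 with a pseudocount of 0.1). The 2-fold counts were 364 higher and 46 lower under the lane term, 516 and 110 with a pseudocount of 0.1 and 423 and 71 with quantile normalization, and array weights gave 8267 changed genes. The count of lower genes was 1257 without iN_LM replicate 1, 1225 without iN_LM replicate 2 and 1202 without iN_BEM replicate 1. The total was 2681 without iN_BEM replicate 1, and the 2-fold lower count 53 without iN_BEM replicate 2.

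**Figure D2:**
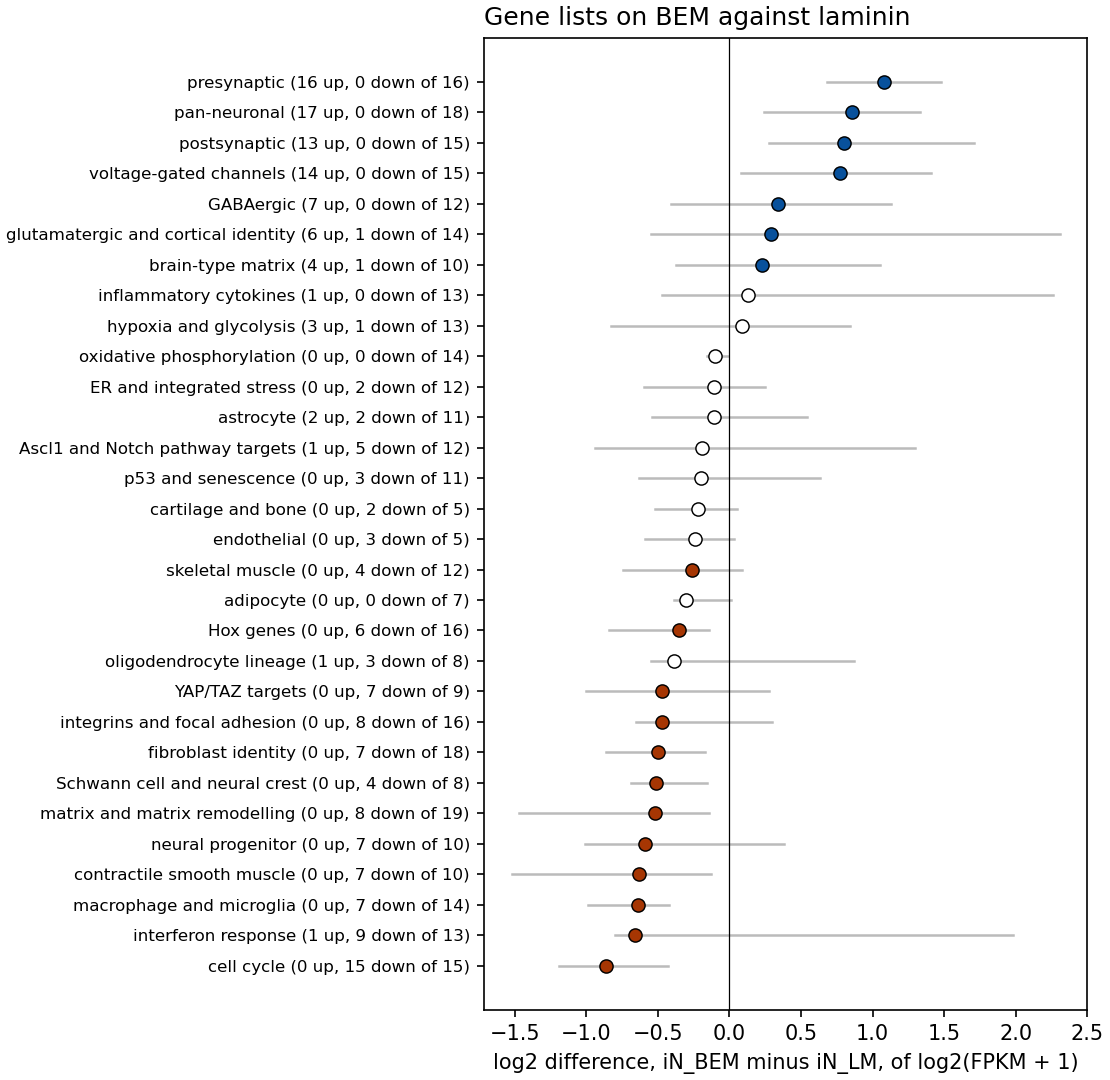
Median log2 difference (iN_BEM minus iN_LM, horizontal axis) of the members of each of the 30 gene lists tested, with grey lines from the lowest to the highest member and, beside each name, the members called higher and lower of those tested. Filled points (blue higher, brown lower) passed camera with its preset correlation and open points did not. The presynaptic list had the highest median (1.08) and the cell cycle list the lowest (-0.86).

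Genes that differ between neurons and fibroblasts were then followed in the substrate comparison. The log2 differences of these 2 contrasts share no library. Their calls do share the spread of each gene, estimated from all 12 libraries, so sets and calls are not fully independent. Of the 1408 genes at least 4-fold higher in PNeuron than in PMEF, 964 rose and 64 fell on BEM against laminin, with a median of 0.60 (camera p = 6.55e-56, and p = 0.00352 with an estimated correlation). Of the 1693 genes at least 4-fold lower in PNeuron, 13 rose and 677 fell (0.7679% and 39.99%, against 1.477% and 64.62% with the replicate block), with a median of -0.35 (camera p = 1.42e-20, and p = 0.089 with an estimated correlation). Neuron-high genes named above that rose included Mapt, Snap25 and Neurod6, and fibroblast-high genes that fell included Tagln, Serpine1 and Ctgf. Along a line from the PMEF mean (0) to the PNeuron mean (1) over the 13788 genes, iN_LM libraries lay at 0.559 ± 0.015 (SD, n = 3, range 0.543 to 0.573). The iN_BEM libraries lay at 0.685 ± 0.024 (range 0.657 to 0.7). The PMEF and PNeuron libraries, each placed with itself left out of its group mean, lay at 0.008 ± 0.04 and 0.995 ± 0.018. All 3 iN_BEM libraries lay above all 3 iN_LM libraries, by 0.126 on average (two-sided exact permutation test, p = 0.1, the smallest that 3 against 3 can give). With the lane term the share of neuron-high genes called higher was 39.28%, against 68.47%, and the share called lower 0.7757%, against 4.545%. The share of fibroblast-high genes called lower, 39.99%, was 5.655% with the lane term, 19.24% without iN_LM replicate 1, 23.85% without iN_LM replicate 2, 19.83% without iN_BEM replicate 1 and 24.04% without iN_BEM replicate 3.

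**Figure D3:**
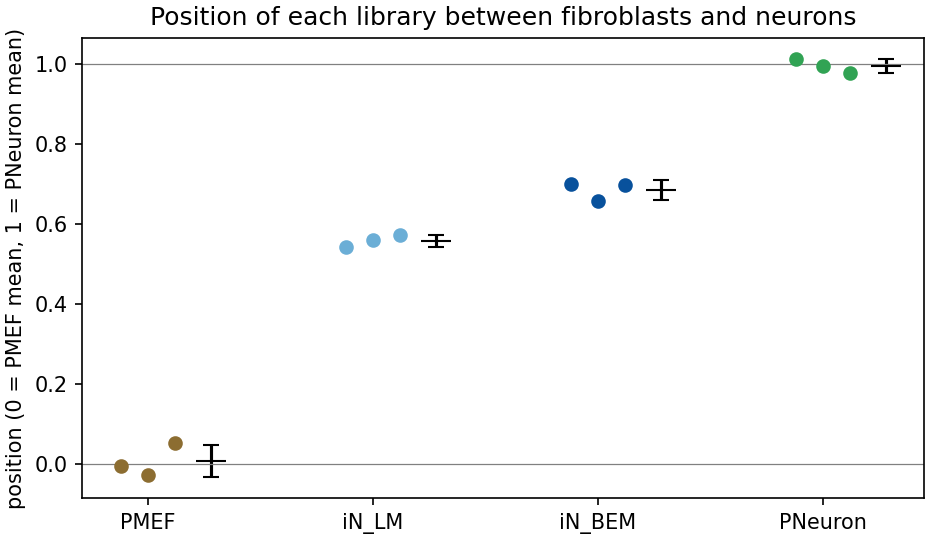
Position of each library on the line from the PMEF mean (0) to the PNeuron mean (1) over 13788 genes (no unit), by group, with the group mean and SD (n = 3) beside the points. The iN_LM libraries lie at 0.543 to 0.573 and the iN_BEM libraries at 0.657 to 0.7.

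**Figure D4:**
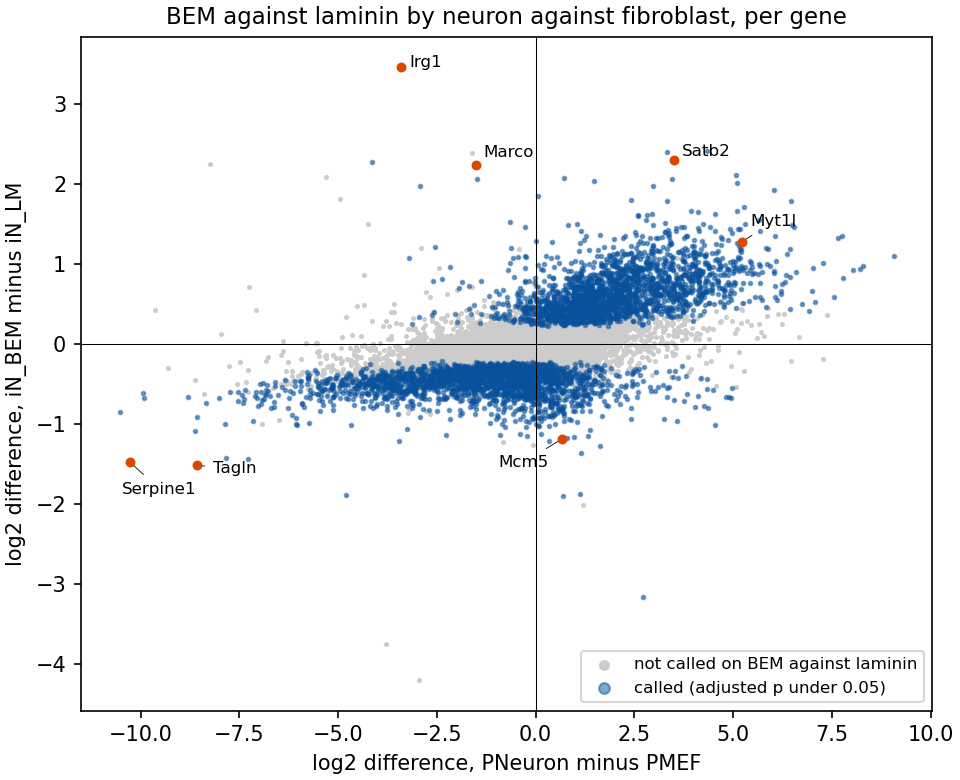
Log2 difference between iN_BEM and iN_LM (vertical axis) against the log2 difference between PNeuron and PMEF (horizontal axis) for the 13788 genes tested, with the 4181 genes called between the substrates in blue and 7 genes named. Of 1408 genes at least 4-fold higher in neurons 964 were called higher on BEM, and Mcm5 and Irg1 lie off that trend.

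Against primary neurons, the cells on laminin showed what remained different. Lyz2 was at 2380.0 ± 127 FPKM in iN_LM and 5.75 ± 3.05 in PNeuron (8.56 ± 0.26), and the imprinted noncoding RNA H19 at 1868 ± 306 and 8.63 ± 2.07 (7.61 ± 0.18). The acute-phase gene Saa3 (7.53 ± 0.74) and the imprinted growth regulator Dlk1 (7.46 ± 0.18) were also higher. Genes lower than in the neurons included Dync1i1 (-3.11 ± 0.14), Sla (-2.70 ± 0.16), the projection-neuron factor Bhlhe22 (-2.66 ± 0.10) and Camkv (-2.64 ± 0.17). All 18 pan-neuronal, 16 presynaptic and 15 postsynaptic genes were lower (the same counts adjusted over the list alone), with medians of -1.17, -1.32 and -1.15. Mapt stood at -1.88 ± 0.13, Snap25 at -2.01 ± 0.12 and Gria2 at -1.77 ± 0.18. Camera gave adjusted p = 1e-07, 1.68e-07 and 3.64e-06 for these lists. They had adjusted p = 0.162, 0.177 and 0.162 with an estimated correlation. Cortical identity genes were lower in 11 of 14 cases (11 adjusted over the list alone), Satb2 at -2.42 ± 0.11 and Foxg1 at -1.70 ± 0.18 (camera adjusted p = 3.28e-05, and adjusted p = 0.162 with an estimated correlation). Fibroblast identity genes were higher in 18 of 18 cases and matrix genes in 19 of 19 (the same counts adjusted over the list alone), Col1a1 at 5.93 ± 0.30 and Mmp2, a gelatinase, at 5.85 ± 0.16. Camera adjusted p was 4.68e-12 and 1.95e-11, and adjusted p = 0.162 with an estimated correlation for each. All 12 skeletal muscle genes were higher (12 adjusted over the list alone), Actc1 by 4.56 ± 0.14 and Mylpf by 3.58 ± 0.11. This list kept its call with an estimated correlation (camera adjusted p = 3.07e-08 preset and 0.00779 estimated). All 14 macrophage and microglia and all 7 adipocyte markers were higher as well (14 and 7 adjusted over the list alone), Tyrobp by 5.73 ± 0.22 and Fabp4 by 6.45 ± 0.15. For these markers camera adjusted p was 7.54e-09 and 1e-04, and adjusted p = 0.162 and 0.177 with an estimated correlation. Only 2 of 15 cell cycle genes differed, both higher, Plk1 by 0.39 ± 0.11 and Ccnb2 by 0.35 ± 0.10 (2 adjusted over the list alone, camera adjusted p = 0.774). Here 8593 genes differed, 4265 higher and 4328 lower in iN_LM, and 2295 and 853 by at least 2-fold. Genes named as different had at most an adjusted p of 0.00704 (Plk1). Camera called 16 lists higher and 7 lower, 1 with an estimated correlation (7 at an unadjusted p under 0.05), and 28 of 30 passed fry. After quantile normalization, which moved the median gene to -0.211, the split was 3462 higher and 6111 lower, and the 2-fold lower count 1567. The astrocyte list (6 higher and 1 lower of 11, the same adjusted over the list alone, camera adjusted p = 0.0482, and adjusted p = 0.177 with an estimated correlation) lost its call with the replicate block (0.0791) and without PMEF replicate 1 (0.0516), PNeuron replicate 3 (0.0537), iN_BEM replicate 3 (0.053) or all replicate 3 libraries (0.0634). That call also ended with an FPKM of at least 5 (0.193), quantile normalization (0.0808), array weights (0.0595), a pseudocount of 0.1 (0.0563), the 2 groups alone (0.0508) and the lane term (0.0506). The lane 9 pair, iN_LM replicate 2 and PNeuron replicate 2, gave medians of -1.33 for presynaptic and 4.33 for fibroblast identity genes.

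The cells on BEM were compared with primary neurons in the same way. Mapt was at 183 ± 14.7 FPKM in iN_BEM and 272 ± 60.4 in PNeuron (-0.55 ± 0.13, adjusted p = 0.00372). Satb2 was at 27.0 ± 3.33 and 29.2 ± 3.48 (-0.11 ± 0.11, adjusted p = 0.415), and both genes were chosen after their values were seen. Lower genes under the naming rule were Hbb-y (-1.93 ± 0.34), the cystine transporter gene Slc7a11 (-1.91 ± 0.22), the polyamine enzyme gene Odc1 (-1.86 ± 0.14), Nxph2 (-1.81 ± 0.16) and Slc16a6 (-1.64 ± 0.11). Lyz2 (8.09 ± 0.26), Saa3 (7.62 ± 0.74), H19 (7.14 ± 0.18) and Dlk1 (6.94 ± 0.18) were higher. Pan-neuronal genes were lower in 12 of 18 cases (12 lower and 1 higher adjusted over the list alone), Rbfox3, the gene of the NeuN antigen, at -0.91 ± 0.13 and Elavl3 at -0.78 ± 0.13, with a list median of -0.44. The list had camera adjusted p = 0.00427, and adjusted p = 0.322 with an estimated correlation. Presynaptic genes were lower in 6 of 16 cases (6 adjusted over the list alone), Cplx1 at -0.95 ± 0.17 (camera adjusted p = 0.0122, and adjusted p = 0.407 with an estimated correlation). Postsynaptic genes were lower in 8 of 15 (8 adjusted over the list alone), Nlgn1 (neuroligin 1) at -0.86 ± 0.11 (camera adjusted p = 0.0112, and adjusted p = 0.33 with an estimated correlation). Cortical identity genes were lower in 11 of 14 cases and higher in 1 (11 and 1 adjusted over the list alone), Fezf2 at -1.41 ± 0.13 and Bcl11b at -1.27 ± 0.12, factors of deep-layer neurons (camera adjusted p = 1.57e-04, and adjusted p = 0.127 with an estimated correlation). GABAergic genes were lower in 6 of 12 cases and higher in 2 (6 and 2 adjusted over the list alone), with a median of -0.34. That list did not pass (camera adjusted p = 0.175), and its highest member was Npy, at 2.63 ± 0.12. All 15 cell cycle genes were lower (15 adjusted over the list alone), Rrm2 at -1.21 ± 0.13 and Mcm5 at -1.10 ± 0.09 (camera adjusted p = 1.92e-06, and adjusted p = 0.127 with an estimated correlation). So were 9 of 10 progenitor genes with 1 higher (9 and 1 adjusted over the list alone), Sox3 at -1.48 ± 0.19 (camera adjusted p = 0.00277, and adjusted p = 0.127 with an estimated correlation). Fibroblast identity and matrix genes were higher in 18 of 18 and 19 of 19 cases (the same counts adjusted over the list alone), Col1a2 by 5.44 ± 0.19 and Mmp2 by 5.28 ± 0.16. These lists had camera adjusted p = 2.12e-14 and 4.4e-13, and adjusted p = 0.111 and 0.127 with an estimated correlation. All 12 skeletal muscle genes were higher (12 adjusted over the list alone), Myog by 2.55 ± 0.13, with camera adjusted p = 1.3e-09 preset and 0.00444 with an estimated correlation. So were all 14 macrophage and microglia markers (14 adjusted over the list alone), Cd68 by 5.01 ± 0.25 (camera adjusted p = 4.25e-10, and adjusted p = 0.127 with an estimated correlation). In this comparison 7401 genes differed, 3777 higher and 3624 lower in iN_BEM, and 1888 and 119 by at least 2-fold. Among the genes named as different the highest adjusted p was 0.00372 (Mapt). Camera called 16 lists higher and 8 lower of 30, 1 with an estimated correlation (11 at an unadjusted p under 0.05), and 28 passed fry. Quantile normalization moved the median gene to -0.215 and the split to 2863 higher and 5833 lower, with 511 lower by 2-fold. It ended the calls of the pan-neuronal (camera adjusted p = 0.171), presynaptic (0.203) and postsynaptic (0.0749) lists. With a lane term 3950 genes were called, 1264 of them lower. The presynaptic call ended there (0.0874) and without PNeuron replicate 1 (0.0626), as did the postsynaptic call with the lane term (0.0616) and, of the genes named, those of Mapt (0.216) and Cplx1 (0.0712). The lane 9 pair, iN_BEM replicate 1 and PNeuron replicate 2, gave medians of -0.36 for pan-neuronal, -0.21 for presynaptic and -0.68 for cell cycle genes.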

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

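Of the tests weighed in this part only the length and GC test was written before its result was seen, the splits were also planned, and all others were chosen only after the result was seen. A difference between groups singled out 5 results: 5 named proliferation genes were higher than in PMEF on laminin and lower than in PMEF on BEM, each passing limma. In the fixed cell cycle list 8 of 15 members were higher and 4 lower on laminin than in PMEF (camera adjusted p = 0.454). The test of the difference was the iN_BEM against iN_LM contrast itself. These genes had been named for their large differences in that contrast, so it gave no separate support. Log2 values of that contrast were -1.03 for Ccnb1, -1.0 for Mcm2, -1.22 for Mcm3, -1.19 for Mcm5 and -1.18 for Uhrf1. Against PMEF these genes stood at 0.42, 0.45, 0.52, 0.75 and 0.89 on laminin and at -0.61, -0.55, -0.69, -0.44 and -0.28 on BEM. The Ccnb1 call on laminin ended without PMEF replicate 1, iN_LM replicate 2 or iN_LM replicate 3 (adjusted p up to 0.0996) and with the lane term (0.116). The Uhrf1 call on BEM ended without PMEF replicate 1 or 2 or iN_BEM replicate 2 or 3 (up to 0.0995), with the 2 groups alone (0.0671), quantile normalization (0.106), median-of-ratios scaling (0.289) and the lane term (0.268), and the Ccnb1 call on BEM with quantile normalization (0.228). Over all genes 38 went opposite ways, 27 of them higher on laminin and lower on BEM, and 0 did so by 2-fold in both. Groups of 3 libraries were not tested for outlying samples.

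Cortical genes in the induced neuronal libraries might come from conversion or from RNA or cells of a cortical preparation. Of 373 genes with a mean of at least 10 FPKM in PNeuron and at most 0.5 in PMEF, 0.2681% lay under 0.25 of the median iN_LM to PNeuron ratio (0.397, and 0.685 in iN_BEM), so few lagged far behind. A cortical source needs this, but whether conversion could give it too was not tested, so it does not decide the source. Of 262 genes with these limits reversed, 25.19% lay under 0.25 of the median iN_LM to PMEF ratio. That set measures fibroblast RNA, so it is no control for the 373 genes. Cell types were not in step, with median iN_LM ratios of 0.321 (excitatory neurons), 0.396 (intermediate progenitors), 0.569 (interneurons), 0.658 (radial glia), 0.719 (Cajal-Retzius cells) and 1.5 (choroid plexus, 5 genes), and members at 0.159 to 7.2. Another preparation need not have the cell mix of PNeuron, so this does not count against a cortical source. For conversion the 4 choroid plexus genes at least 10-fold above PMEF in iN_LM cannot tell, since no fibroblast culture kept for 30 days without the delivered factors is among the samples. Quantile normalization left a median log2 difference of iN_LM from PMEF of 2.55 over the 373 genes. These genes were picked as near absent in PMEF, so a test of the scaling on them could hardly turn out otherwise. A larger share of RNA with the profile of the PNeuron libraries is excluded as the whole cause of the substrate difference, because 26 genes lay at least 2-fold outside both iN_LM and PNeuron (17 above, 9 below). A share of 0.35 removed 54.11% of the variance of that difference, so such a share is not excluded as a part of it, a larger share of neurons with another profile was not tested, and the source of the cortical genes stays open.

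Irg1, Il1a, Marco, Ccl5 and Cxcl10 were higher on BEM than on laminin, which are 5 genes grouped after their values were seen and not a list fixed beforehand. In PMEF replicates 1 and 2 Irg1 (32.3 and 36.2 FPKM), Il1a (42.8 and 48.2) and Cxcl10 (22.2 and 22.0) exceeded their iN_BEM levels (at most 15.5, 5.97 and 14.4). Marco and Ccl5 did not, and in PMEF replicate 3 all 5 genes were lower than in iN_BEM. The macrophage and microglia list had a median of -0.64, with members at -0.99 to -0.42 and 7 of 14 called lower, so these markers gave no sign of a larger macrophage share. That list had an adjusted p of 0.358 by camera with an estimated correlation. Marker RNA cannot tell the number of macrophages from their state, so a larger share is not excluded. Sequencing lane is excluded as the whole cause, since the ranges within iN_LM and iN_BEM, each over 2 lanes, summed to at most 0.348 of a gene's difference, where lane alone needs 1.5. The lane term still ended all 5 calls (adjusted p = 0.148, 0.311, 0.321, 0.139 and 0.292), because the standard errors were larger (0.54 to 0.76 without it and 0.91 to 1.3 with it), while the log2 differences were 1.98 to 3.46 without it and 2.02 to 3.27 with it. Variation between cultures of a group could also give the values, and the test cannot tell it from an effect of BEM: the median range of the 5 genes was 3.61 on the log2 scale in PMEF, but 0.42 in iN_LM, 0.27 in iN_BEM and 0.26 in PNeuron, against a median difference between the substrates of 2.24.

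Replicate 3 lay farther from replicates 1 and 2 than these lay from each other in all groups, though only 1.184 times as far in PNeuron. A length or GC bias of the replicate 3 libraries may account for much of this. The mean correlation between groups of the replicate 3 deviations was 0.56, and 0.24 after removal of a trend on length and GC, as that explanation predicts. Across the groups the Spearman correlation of these deviations was -0.61 (PMEF) to -0.83 (iN_BEM) with GC content. With length it was only 0.08 (PNeuron) to 0.31 (iN_LM), so the deviations followed GC more closely. Sequencing lane is excluded, since in PMEF, all in lane 9, replicate 3 still lay 1.839 times as far as replicates 1 and 2 lay from each other. No biological explanation was tested, and what set these libraries apart stays open.

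The 6 libraries of each comparison can be split 10 ways, too few for a share under 0.05, so the splits cannot tell the grouping from chance. Only the real split gave as many calls (1 of 10) in each comparison, with real counts of 4181 (iN_BEM against iN_LM), 10572 (iN_LM against PMEF), 11147 (iN_BEM against PMEF), 11430 (PNeuron against PMEF), 8593 (iN_LM against PNeuron) and 7401 (iN_BEM against PNeuron), and the highest other split gave 1 gene for PNeuron against PMEF and 0 in the others.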

How the results depend on the processing

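All alternatives were planned except leaving out all replicate 3 libraries, which was chosen after the data were seen. No named gene turned direction, and 2 list results did, both of the oxidative phosphorylation list. With the lane term 32 calls of named genes ended, under every other setting at most 7, and genes below a stricter filter have no value there. Calls of lists that ended with the direction kept numbered 133 with an estimated correlation, 14 with quantile normalization, 9 with an FPKM of at least 5 and at most 4 under any other setting. The 2 results that turned direction, under quantile normalization, lost their calls as well. For every change below the cause was not tested. With the lane term the iN_BEM level rests on iN_BEM replicate 1, the only iN_BEM library outside lane 2. Its losses in contrasts with iN_BEM therefore cannot separate a lane effect from lost information. Unknown depth limits what can be said of genes with low values. For iN_BEM against iN_LM (4181 changed, 2037 higher, 2144 lower, 260 and 34 by 2-fold) array weights gave 8267 changed, 3455 higher and 4812 lower, and the lane term 1224, 852 and 372. A pseudocount of 0.1 gave 516 higher and 110 lower by 2-fold and quantile normalization 423 and 71. With single libraries left out the ranges were 2681 to 4784 changed, 1202 to 2557 lower and 30 to 53 lower by 2-fold. The replicate block gave 6977 changed and 3942 lower, and for fibroblast-high genes 1.477% higher and 64.62% lower. In the comparisons that reached the limit for pairing it also gave Pou3f2 a call between the substrates (adjusted p = 0.0256) and ended that of the astrocyte list in iN_LM against PNeuron (0.0791). The block changed no other call of a named gene or list there. In the contrasts with PMEF, which did not reach that limit, the block gave 11695 (iN_LM), 12014 (iN_BEM) and 12208 (PNeuron) genes, and the inflammatory cytokine list in iN_BEM had an adjusted p of 0.0603. There 4, 5 and 4 of 6 libraries correlated best with their own number. The comparisons that reached the limit did no better, with 3, 4 and 4 of 6 in iN_BEM against iN_LM, iN_LM against PNeuron and iN_BEM against PNeuron. An estimated correlation left 0 lists in iN_BEM against iN_LM and in each contrast with PMEF and 1 in each contrast with PNeuron, and gave p = 0.089 for fibroblast-high genes. Quantile normalization gave 1567 genes lower by 2-fold in iN_LM against PNeuron, and 5833 lower and 511 lower by 2-fold in iN_BEM against PNeuron, an axis difference of 0.153, and turned the oxidative phosphorylation list to higher against PMEF in iN_LM (camera adjusted p = 0.331) and iN_BEM (0.4). In iN_BEM against PNeuron the lane term gave 3950 changed and 1264 lower and a pseudocount of 0.1 gave 214 lower by 2-fold. For neuron-high genes the lane term gave 39.28% higher and 0.7757% lower (68.47% and 4.545% in the fit as reported), and leaving out single libraries 2.912% to 4.871% lower. For fibroblast-high genes (0.7679% higher and 39.99% lower) the 2 groups alone gave 1.749% higher, array weights 3.211% and 68.39% lower, the lane term 0.2381% and 5.655%, all replicate 3 libraries left out 2.399% higher, and single libraries left out 0.4132% to 2.616% higher and 19.24% to 51.64% lower. Without all replicate 3 libraries 5039 genes changed between the substrates.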

Other observations

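All genes named in this part were chosen after their values were seen. They come from no list fixed beforehand, so nothing is said of the groups they belong to. The imprinted gene H19 was at 47.3 ± 2.77 FPKM in PMEF, 1868 ± 306 in iN_LM, 1359 ± 289 in iN_BEM and 8.63 ± 2.07 in PNeuron (mean ± SD, n = 3 libraries), and Igf2, an insulin-like growth factor gene, at 119 ± 10.7, 1062 ± 159, 728 ± 138 and 41.9 ± 5.69 in the same order. Dlk1 was at 4.02 ± 0.577, 321 ± 74.8, 223 ± 47.9 and 0.792 ± 0.0770 FPKM, and Cdkn1c, a cyclin-dependent kinase inhibitor gene, at 12.4 ± 0.388, 153 ± 30.2, 129 ± 31.9 and 12.7 ± 2.48. Against PMEF the log2 differences on laminin were 5.26 ± 0.18 for H19, 3.14 ± 0.15 for Igf2, 5.98 ± 0.18 for Dlk1 and 3.50 ± 0.19 for Cdkn1c (limma, highest adjusted p = 3.25e-09, for Cdkn1c). Against PNeuron they were 7.61 ± 0.18, 4.63 ± 0.15, 7.46 ± 0.18 and 3.49 ± 0.19 (highest adjusted p = 5.62e-09, for Cdkn1c). Levels on BEM were lower than on laminin for Igf2 (-0.55 ± 0.15, adjusted p = 0.0167, and 0.0768 at most without iN_LM replicate 1 or iN_BEM replicate 3, each of which ended the call, as did quantile normalization, 0.07, and the lane term, 0.298), while Cdkn1c differed by -0.25 ± 0.19 (adjusted p = 0.349).

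Apoe, the apolipoprotein E gene, was at 50.1 ± 2.02 FPKM in PMEF, 1447 ± 286 in iN_LM, 1061 ± 320.0 in iN_BEM and 60.1 ± 39.8 in PNeuron, a log2 difference of 4.81 ± 0.34 on laminin and 4.34 ± 0.34 on BEM against PMEF (adjusted p = 3.79e-08 and 8.17e-08, limma). Trem2, a microglial lipid receptor gene, was at 4.16 ± 1.16, 55.2 ± 11.9, 31.5 ± 7.23 and 0.631 ± 0.478 FPKM, and Arg1, the arginase 1 gene, at 1.01 ± 0.361, 20.1 ± 1.48, 8.64 ± 1.96 and 0.0608 ± 0.0452, with a difference between the substrates of -1.14 ± 0.15 (adjusted p = 1.89e-04).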
